A study of Mus musculus with 20 samples.

How the data were processed

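Islets were isolated from the pancreas by enzyme digestion, picked under a microscope and kept in culture overnight before RNA was taken, per the labels' protocols. RNA-seq libraries were made with a TruSeq RNA v2 kit, which does not mark strand. The deposited values are DESeq-normalized read counts per gene, per the file's name, and were handled here as a signal unit, that is gene read counts divided by a size factor for each library. The submitters' processing notes name FastQC, TopHat 1.3.3, Bowtie 0.9.9, Cufflinks 1.3.0 and DESeq 1.16.0 with the mouse build mm9, without a role or order. The read counter, its strand setting, its treatment of reads with several matches and the annotation version are not given in the sources used here.

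The table held 26211 genes under Ensembl identifiers, none of them at 0 in every library, and the columns of all 20 libraries were used. Knockout columns carried the replicate numbers of the labels, 1 to 10. Wild-type columns carried the numbers 11 to 20, whereas the labels number wild-type samples 1 to 10, so they were used as wild-type libraries without a replicate number of their own. Names were taken from GENCODE M21, which gave 23950 names and left 2261 identifiers unnamed. GENCODE M21 is on GRCm38 and not on mm9, so it was used for names, chromosomes, gene types and neighbours, and no coordinates are printed.

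In each column the values were whole multiples of a single step, and dividing by it returned whole reads for 100% of the non-zero values within a tolerance of 0.05 reads. Depth therefore ranged from 34520628 to 199847246 reads over genes. Deeper libraries measure low genes with less counting error, and at these depths differences between libraries of the same group exceeded counting error, as the chi-square values over genes with at least 20 reads in a pair showed.

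The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean trend, on log2 of the value plus a pseudocount of 1. Genes with a mean value of at least 10 over the 20 libraries were tested, with genotype as the only term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were counted. Fold changes are on this scale, on which the pseudocount understates the change of genes that are low in all libraries. A difference of mean log values can also exceed the ratio of means where some libraries are near 0, as for P2ry14 and Rps13-ps1. A difference in the P2ry14 mean was tested by a two-sided permutation test with 100000 resamples, whose smallest p is 2e-05. Of 25 gene lists, 23 were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists. The sex-linked genes and the genes around P2ry14 were described and not counted. Of the 673 list entries, 661 were in the table, and the others, Kcnj11 among them, were not analysed here. Some genes stand in more than 1 list.

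The tests, the lists, the alternatives planned and the rule for the named genes were chosen before the data were examined. The rule took P2ry14, then the 12 higher and 12 lower genes with the largest absolute log2 fold change among genes past the threshold with a mean value of at least 50. From each list that was past the threshold, or had a member past it, up to 4 members with the smallest p were taken. From each other list the 1 or 2 members with the highest mean were taken, and Ins1, Ins2, Gcg, Sst and Ppy always. The values of some genes that the rule takes are not reported here.

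The alternatives were other pseudocounts (0.5 and 10), no filter on low values or a mean of at least 100, TMM factors, quantile normalization, robust eBayes, library weights, a rank test with a normal approximation and an exact one, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and covariates for Xist, acinar RNA and the first surrogate variable of sva 3.50.0. Each library was also left out in turn. Tests of single values were run in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. On the recovered reads, edgeR's quasi-likelihood test gave 43 genes past the adjusted p and DESeq2 gave 137.

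The limma step was tested on simulated data with the depth and spread of 10 knockout against 10 wild-type libraries over 17220 genes, of which 193 were changed. It recovered 24% of genes changed by 1.5-fold, 60.9% of those changed by 2-fold, 81.2% of those changed by 3-fold and 85.7% of those changed by 4-fold, and 6 of its 127 calls were false. Each gene was drawn independently, without the shared variation in acinar RNA or an outlying library, so these rates may not hold for the real libraries.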

Results

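Messenger RNA was sequenced from pancreatic islets, the endocrine cell clusters of the pancreas, of mice lacking P2Y14 and of wild-type mice. P2Y14, encoded by P2ry14, is a G protein-coupled receptor for UDP and UDP-sugars, and the series title places the study around insulin release. There were 10 knockout and 10 wild-type libraries, all labelled with the mixed strain C57BL/6 x 129S6. Reads summed over genes ranged from 34520628 in knockout replicate 5 to 199847246 in knockout replicate 4, with medians of 92323083 in knockout and 105776893 in wild-type. The labels do not say that each library came from its own animal, so the p-values measure the spread between these samples. Each of the 90 pairs of libraries of the same group differed by more than sampling noise, the lowest chi-square per degree of freedom being 76.7.

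P2ry14 (ENSMUSG00000036381, chromosome 3) was lower in knockout islets, at a normalized read count of 51.2 ± 31.4 (SD, n = 10) against 151 ± 67.4 (SD, n = 10) in wild-type. The ratio of the means was 0.340, and a two-sided permutation test of the difference in means gave p = 4e-05. The knockout replicates 1 to 10 had normalized read counts of 40.7, 113.5, 39.9, 29.5, 0, 61.7, 48.8, 34.8, 57.2 and 86.0. The wild-type libraries 11 to 20 had 262.1, 79.7, 253.4, 157.4, 113.0, 123.8, 209.4, 110.1, 88.7 and 109.3. Thus 8 of the 10 knockout libraries lay below the lowest wild-type library, and knockout replicates 2 and 10 overlapped with the wild-type range. Knockout replicate 5, the shallowest library by total reads, had 0 reads, which allows a normalized read count of up to 4.62, for counting error only. Its size factor of 0.650 was above those of knockout replicates 6 and 7, 0.389 and 0.491, which had 24 reads of P2ry14 each. In the fit over all genes the log2 fold change of P2ry14 was −1.97 (SE 0.59), with an adjusted p of 0.244 by limma. That adjusted p was 0.0283 without knockout replicate 5, 0.0144 with DESeq2 and 0.0339 with acinar RNA as a covariate. P2ry14 lies inside Med12l on the opposite strand, the library kit does not mark strand, and which part of P2ry14 was deleted is not given in the sources used here. Reads from any stretch counted for both genes can therefore not be told apart by strand. The reads left in knockout libraries do not show whether a P2ry14 transcript remained. Knockout replicate 5 had 0 reads of P2ry14 although Med12l was at 490 or more in every library. In that library, Med12l reads were thus not counted for P2ry14. Med12l itself had 939 ± 311 (SD, n = 10) in knockout and 1086 ± 386 (SD, n = 10) in wild-type, with an adjusted p of 0.832 by limma.

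**Figure D1:**
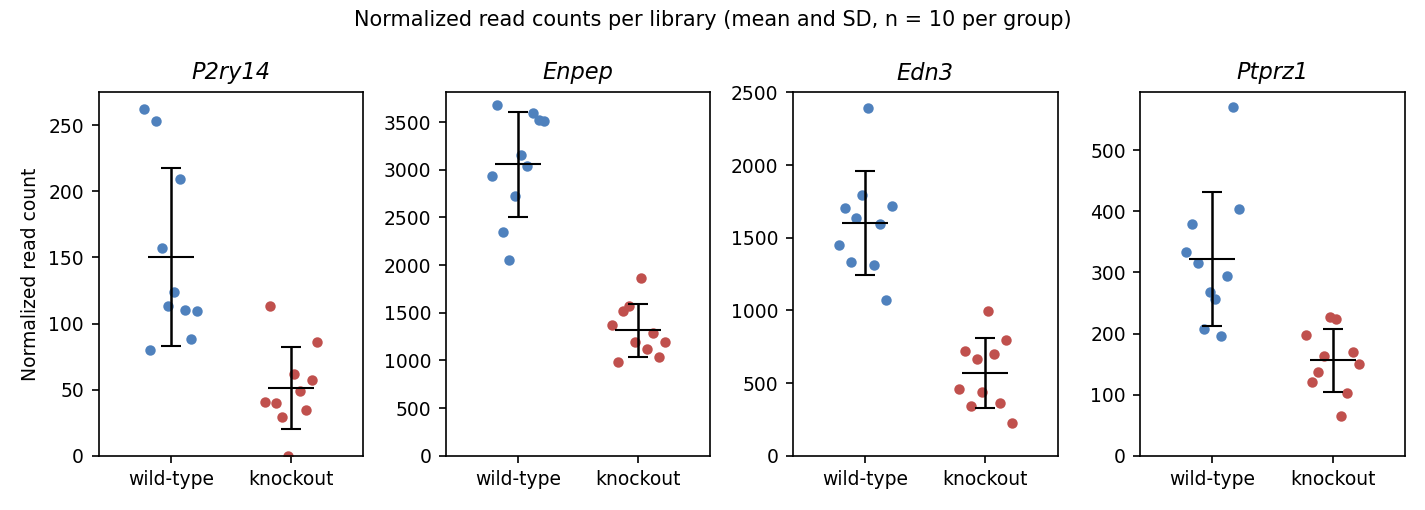
Normalized read counts of P2ry14, Enpep, Edn3 and Ptprz1 in each of the 10 wild-type and 10 knockout libraries, with points for libraries and bars for the mean and SD. For Enpep and Edn3 every knockout library lies below every wild-type library, whereas the groups overlap for P2ry14 and Ptprz1.

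The comparison of knockout with wild-type islets over all genes asked which other transcripts differed. Among 17482 genes tested, 49 differed at an adjusted p under 0.05 by limma, 28 of them higher and 21 lower in knockout. Of these 49, 22 were higher and 14 were lower by at least 2-fold. In 5 of the 49 genes the groups did not overlap, as in 6 of all tested genes, where chance gives 0.00108% of genes. In all, 1563 genes had an unadjusted p under 0.05, and the median log2 fold change over all tested genes was −0.002.

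Among the protein-coding genes lower in knockout, Enpep, which encodes the angiotensin-cleaving glutamyl aminopeptidase, fell from 3057 ± 554 (SD, n = 10) to 1314 ± 273 (SD, n = 10). Its log2 fold change was −1.22 (SE 0.13, adjusted p = 4.76e-05 by limma), in the same direction in 10 of 10 knockout libraries. Edn3, which encodes the peptide endothelin-3, fell from 1602 ± 358 (SD, n = 10) to 571 ± 242 (SD, n = 10), with a log2 fold change of −1.58 (SE 0.22, adjusted p = 5.25e-04 by limma). Thbs3, a thrombospondin of the extracellular matrix, had a log2 fold change of −1.75 (adjusted p = 3.53e-04 by limma). In knockout replicate 6 Thbs3 was at 1234, near the wild-type mean of 1416. The paternally expressed Peg10 (log2 −1.35), the netrin receptor gene Unc5c (−1.21), the receptor tyrosine phosphatase gene Ptprz1 (−1.06), the kinase gene Pak1 (−0.93), the orphan receptor gene Gpr179 (−0.85) and the rhomboid family gene Rhbdl3 (−0.67) were also lower. The calls of Ptprz1 and Gpr179 held in 6 and 5 of the 20 fits that left out 1 library. The same number was 18 for Rhbdl3. The call of Ptprz1 also ended with no filter on low values, without chromosomes 3 and 7 and with Xist or the macrophage list as a covariate, at adjusted p from 0.0503 to 0.0532. That of Gpr179 ended with no filter, among genes with a mean of at least 100, without chromosomes 3 and 7, with quantile normalization and with edgeR, at adjusted p from 0.0507 to 0.0707.

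Among the genes higher in knockout, Myo7a, which encodes an unconventional myosin of sensory hair cells, rose from 21.3 ± 25.3 (SD, n = 10) to 841 ± 349 (SD, n = 10). Its log2 fold change was 6.54 (SE 0.84, adjusted p = 3.53e-04 by limma), and knockout replicate 6 had the lowest knockout value, 79.7. Trim12a, a member of the tripartite motif family with a close copy in the same gene cluster, rose by 6.27 on the log2 scale (SE 0.86, adjusted p = 5.25e-04 by limma) and had 0 reads in knockout replicate 6. Its value was 3.64 with a pseudocount of 10. Meox1, a homeobox gene, rose by 1.36 on the log2 scale and 1700029J07Rik by 1.33. Ahcy, which encodes S-adenosylhomocysteine hydrolase, rose by 2.36. Eif3j1 (2.10) and the ribosomal protein gene Rpl34 (1.84) also rose, and both have near-identical copies in the mouse genome, so their values are uncertain. The call of Eif3j1 held in 12 of the 20 fits that left out 1 library and ended with edgeR (adjusted p = 0.0527).

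Several of the largest differences lay in near-identical gene copies and are reported as uncertain, because the counting could assign their reads to other copies. Of the 49 genes, 8 are annotated as pseudogenes. Rps13-ps2, a processed copy of the ribosomal protein gene Rps13 on chromosome 7, was at 978 ± 580 (SD, n = 10) in knockout and 2.15 ± 2.11 (SD, n = 10) in wild-type, a log2 fold change of 7.65 (adjusted p = 3.53e-04 by limma). Rps13-ps1, another copy on chromosome 8, went the other way, at 131 ± 404 (SD, n = 10) against 706 ± 298 (SD, n = 10), with a log2 fold change of −7.14 (adjusted p = 4.72e-04 by limma). The knockout mean of Rps13-ps1 came from knockout replicate 6, at 1280, and its call ended with edgeR (log2 −2.55, adjusted p = 0.529), whereas DESeq2 gave −4.33 (adjusted p = 0.0289). Rps13 itself was at 47.3 in knockout and 50.5 in wild-type. The pseudogenes Gm9826 (log2 4.14), Gm4735 (3.93) and Gm9493 (2.64) were higher, and Hist1h2al (−5.64) was lower. The call of Hist1h2al ended with edgeR (log2 −2.60, adjusted p = 0.495), and with a pseudocount of 10 its value was −2.94 and that of Gm9826 was 2.69. ENSMUSG00000089738, which has no name in the annotation used, was higher by 1.66. Gm16559, annotated as antisense, had a log2 fold change of −0.93, and its reads cannot be separated from an overlapping gene without strand. The calls of ENSMUSG00000089738 and Gm16559 held in 9 and 8 of the 20 fits that left out 1 library, and ended with no filter on low values (adjusted p = 0.0501) and with Xist as a covariate (adjusted p = 0.0519), respectively.

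**Figure D2:**
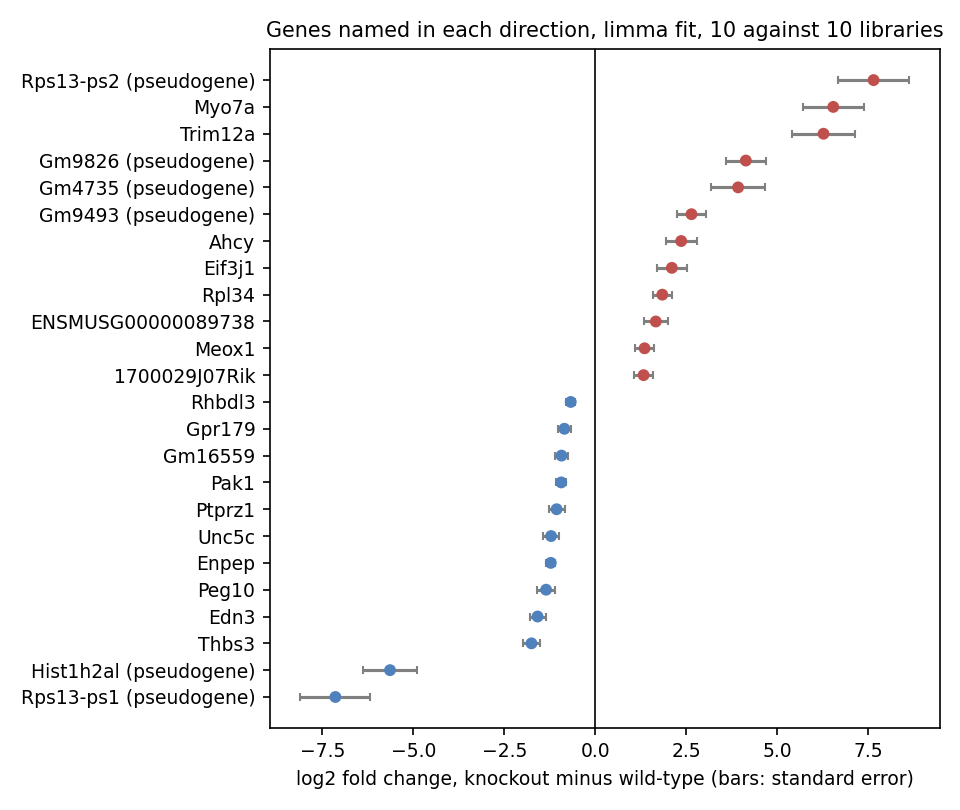
Log2 fold changes, knockout minus wild-type, of the 12 higher and 12 lower genes named by the fixed rule, with bars for the standard error of the limma fit over 10 against 10 libraries. Rps13-ps2 at 7.65 and Rps13-ps1 at −7.14 mark the ends of the range, and both are processed pseudogenes.

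Chromosome 3, which holds P2ry14, carried 10 of the 44 differing genes with a known chromosome, against 2.2 expected from its 5.0% share of tested genes (adjusted p = 0.00113, hypergeometric test over chromosomes). These were Thbs3, Riiad1, Gm42743, Capza1, Ank2, Enpep, Rpl34, Lamtor3, Gm16559 and Unc5c, chosen here for their place and after their values were seen. In the gene order of GENCODE M21 they were numbers 328 to 753 of the 833 tested genes of the chromosome, all on the same side of P2ry14, which was number 174. Chromosome 7 carried 8 against 3.32 expected, with an adjusted p of 0.183. In gene order these ran from number 529 (Fut1) and 716 (Rps13-ps2) to 922 (Plekha7) of its 1257 tested genes. Pak1 and Myo7a were neighbours at 757 and 758. Their closeness was not tested. The list of genes around P2ry14, with 21 tested including P2ry14 itself, had none past the test over all genes and none adjusted over the list alone. Among these neighbours, Tm4sf4 had a log2 fold change of 0.06, from −0.07 to 0.16 when 1 library was left out, and Serp1 one of 0.17. With the genes of chromosomes 3 and 7 left out, 24 genes differed.

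**Figure D3:**
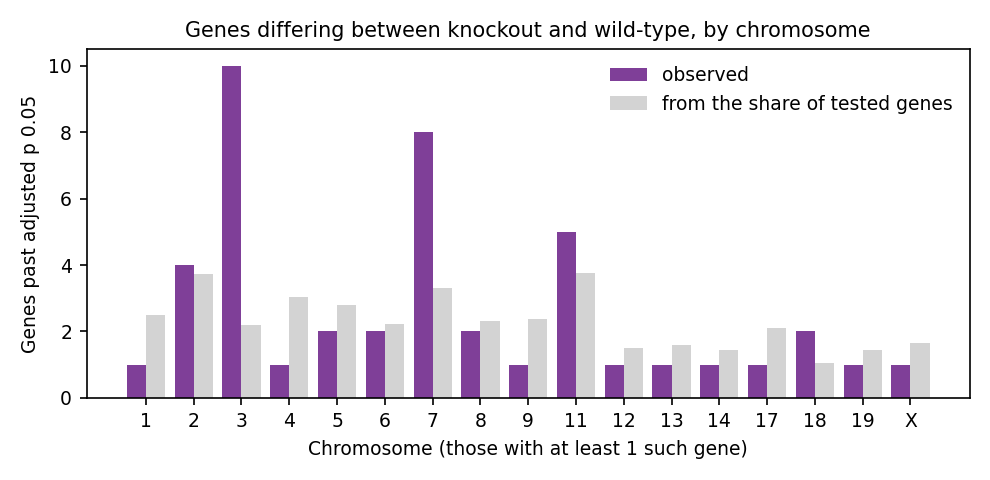
Number of genes past an adjusted p of 0.05 per chromosome beside the number that the chromosome's share of tested genes gives. Chromosome 3 has 10 where 2.2 were expected, and chromosome 7 has 8 where 3.32 were expected.

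The limma count of 49 genes moved by over 1.5 times in several fits. It was 27 without knockout replicate 4, 74 without knockout replicate 6, 32 without knockout replicate 8 or 9, and 31 without wild-type library 19. It was 163 with library weights, 137 with DESeq2, 82 with acinar RNA or a surrogate variable as a covariate, 29 among genes with a mean of at least 100, and 17 in an exact rank test, in which 15 of the 24 genes named above by size were not past the threshold.

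The preset lists of endocrine identity genes had negative median fold changes in knockout, the lowest being that of delta and PP cells, which make somatostatin and pancreatic polypeptide. Of 11 delta and PP cell genes tested, 10 had a negative fold change, with a median log2 of −0.52 (adjusted p = 3.73e-05 by camera with its preset correlation). This was the only list past the threshold with an estimated correlation, at an adjusted p = 0.0265. Over all genes 1 member, Ptprz1, fell; adjusted over the list alone 4 fell. These were Ptprz1, the retinol carrier gene Rbp4 (log2 −0.67), the arginase gene Arg1 (−0.51) and the somatostatin gene Sst (−0.54). Sst was at 78144 ± 26040 (SD, n = 10) in knockout and 109600 ± 26950 (SD, n = 10) in wild-type, with an adjusted p of 0.406 over all genes by limma. Ppy, which encodes pancreatic polypeptide, had a log2 fold change of −0.51 (SE 0.43, adjusted p = 0.753 by limma), which was −0.32 without knockout replicate 5 and −0.08 with DESeq2.

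Of 12 alpha cell genes, 10 had a negative fold change, with a median log2 of −0.45 (adjusted p = 7.23e-04 by camera, and adjusted p = 0.435 with an estimated correlation). The median was −0.28 without knockout replicate 10. None passed over all genes, and 3 fell adjusted over the list alone, among them the homeobox genes Irx1 (log2 −0.65) and Irx2 (−0.56). The glucagon gene Gcg had a log2 fold change of −0.57 (SE 0.24, adjusted p = 0.480 by limma). Of 26 beta cell identity genes, 20 had a negative fold change, with a median log2 of −0.18 (adjusted p = 9.35e-04 by camera, and adjusted p = 0.470 with an estimated correlation). This median was −0.11 without wild-type library 19 or with the macrophage list as a covariate. None of these genes passed over all genes or adjusted over the list alone. The insulin genes had log2 fold changes of 0.16 (SE 0.44) for Ins2 and 0.10 (SE 0.22) for Ins1, neither beyond the spread. With 1 library left out Ins2 ran from 0.07 to 0.25 and Ins1 from 0.05 to 0.20, and Ins2 was at −0.40 with quantile normalization. The transcription factor gene Mafa (−0.55), the channel gene Trpm5 (−0.54) and the incretin receptor gene Glp1r (−0.35) had negative values.

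The lists of the secretory machinery had small negative medians. Of 29 genes of stimulus-secretion coupling, 26 had a negative fold change, with a median log2 of −0.15 (adjusted p = 1.85e-04 by camera, and adjusted p = 0.435 with an estimated correlation), which was −0.23 without wild-type library 20. Adjusted over the list alone only Itpr1, a calcium release channel gene, fell (log2 −0.70), and none did over all genes. The calcium channel gene Cacna1c had −0.55. For 46 genes of cAMP and G protein signalling the median log2 was −0.09 (adjusted p = 0.00556 by camera, and adjusted p = 0.435 with an estimated correlation), with Gnas at −0.33, Pde4b at −0.45, Pde4d at −0.46 and Pde1c at −0.60. For 44 genes of vesicle exocytosis it was −0.11 (adjusted p = 0.0248 by camera, and adjusted p = 0.586 with an estimated correlation), with Sytl4 at −0.36, Stx1a at −0.28 and Rph3al at −0.25. None of the members of either list passed over all genes or adjusted over the list alone. The call of the exocytosis list ended without knockout replicate 2, 8 or 10 or wild-type library 11, 16 or 19, at adjusted p of 0.0817, 0.0577, 0.221, 0.0826, 0.171 and 0.0572. It ended as well with quantile normalization (adjusted p = 0.0561 by camera) and with the surrogate variable as a covariate (adjusted p = 0.0618).

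Genes of the cell cycle had a negative fold change in 26 of 38, with a median log2 of −0.35 (adjusted p = 9.35e-04 by camera, and adjusted p = 0.435 with an estimated correlation). The median was −0.18, −0.19 and −0.22 without knockout replicates 2, 7 and 10, −0.15 among genes with a mean of at least 100, −0.16 with a pseudocount of 10, and −0.22 with quantile normalization or DESeq2. Adjusted over the list alone 2 fell, the replication licensing gene Mcm4 (log2 −0.61) and the mitotic kinase gene Plk1 (−2.22), and none did over all genes. Top2a (−0.95) and Cenpf (−1.95) had negative values. With a pseudocount of 10 Plk1 was at −1.09 and Cenpf at −1.15.

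The lists of oxidative phosphorylation and of the ER stress response had small positive medians. Of 43 genes of oxidative phosphorylation, 41 had a positive fold change, with a median log2 of 0.16 (adjusted p = 1.59e-04 by camera, and adjusted p = 0.586 with an estimated correlation), which was 0.09 without knockout replicate 10 and 0.08 with the macrophage list as a covariate. None passed over all genes or adjusted over the list alone, and Cox4i1 (0.48), Ndufb9 (0.41), Sdhb (0.37) and Cox6c (0.29) had the smallest p. Of 27 genes of the ER stress response, 18 had a positive fold change, with a median log2 of 0.06 (adjusted p = 0.0141 by camera, and adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 4 rose, namely Ddit3 (0.64), Chac1 (0.85), Atf4 (0.30) and Trib3 (1.08), and none did over all genes. This call ended without knockout replicate 2 or 6 or wild-type library 14, at adjusted p of 0.157, 0.0964 and 0.0515. The median was 0.03 without knockout replicate 2, 0.10, 0.11 and 0.10 without knockout replicates 1, 5 and 10, and 0.10 and 0.09 without wild-type libraries 13 and 19.

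Transcripts of other cell types were measured alongside. Macrophage and dendritic cell genes had a positive fold change in 22 of 29, with a median log2 of 0.36 (adjusted p = 9.35e-04 by camera, and adjusted p = 0.586 with an estimated correlation), which was 0.22 without wild-type library 19. None passed over all genes or adjusted over the list alone, and Aif1 (1.37), Adgre1 (0.95), Tyrobp (0.74) and Itgax (0.71) had the smallest p. Aif1 was at 0.87 without wild-type library 20. With this list as a covariate the calls of the exocytosis and cAMP lists ended, at adjusted p of 0.156 and 0.0533. The acinar genes listed, of the enzyme-secreting exocrine cells, took 22.6 ± 9.06% of reads (SD, n = 10) in knockout and 21.5 ± 8.92% (SD, n = 10) in wild-type, a difference within the spread (permutation test p = 0.786). Acinar RNA outside the list was not summed. The acinar list had an adjusted p of 0.297 by camera, with Amy1 at a log2 of 0.55 and Ctrb1 at 0.10. With 1 library left out these ran from 0.31 to 0.79 and from −0.16 to 0.36. It was past the threshold without knockout replicate 1, 5 or 9 or wild-type library 13, 14 or 17, at adjusted p of 0.0376, 0.00183, 0.0396, 0.028, 0.048 and 0.0269, and with library weights at 0.0142.

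The remaining lists were not past the threshold by camera. The nucleotide receptors and ectonucleotidases had an adjusted p of 0.211, with Entpd3 at a log2 of −0.06 and Enpp2 at 0.02, and the adenosine receptor gene Adora3 fell adjusted over the list alone (−3.29, adjusted p over all genes 0.157 by limma). UDP-sugar metabolism, which supplies the ligands of P2Y14, had an adjusted p of 0.475 by camera, with Gfpt1 at −0.18 and Uggt1 at −0.03. Adjusted p by camera were 0.822 for the interferon response, 0.568 for inflammation and chemokines, 0.855 for glycolysis and hypoxia, and 0.776 for immediate early genes, endothelial cells and lymphocytes alike. They were 0.989 for ductal cells, 0.895 for mesenchymal cells, 0.757 for glial and neuronal genes and 0.822 for blood. Adjusted over their lists alone, Mx1 of the interferon response (−3.22) and Th of the neuronal list (−0.63) fell and Reg2 of the inflammation list (2.66) rose. The highest expressed members had log2 fold changes of 0.26 for Ifi27, −0.24 for Irf1, 0.66 for Reg1, 0.01 for Aldoa, −0.03 for Vegfa, 0.13 for Hsph1 and −0.08 for Fos. They were −0.12 for Clu, 0.20 for Tff2, −0.10 for Pecam1, 0.35 for Egfl7, −0.13 for Sparc, 0.11 for Col3a1, 0.29 for Ighm, 0.39 for Jchain, −0.01 for Mbp, 0.22 for Hbb-bs and 0.07 for Hba-a2. Leaving out 1 library turned the sign of Entpd3, Enpp2, Uggt1, Aldoa, Vegfa, Fos, Tff2, Pecam1, Col3a1, Ighm, Jchain, Mbp, Hbb-bs and Hba-a2, and edgeR turned that of Clu and Hsph1. With 1 library left out the values ran from −0.23 to 0.84 for Hbb-bs, from −0.34 to 0.70 for Hba-a2, from −0.20 to 0.73 for Ighm, from −0.19 to 1.01 for Jchain and from −0.21 to 0.37 for Col3a1. They ran from 0.16 to 0.47 for Egfl7, from −0.22 to −0.02 for Sparc, from 0.03 to 0.43 for Hsph1, from −0.31 to −0.15 for Irf1 and from −0.29 to −0.07 for Gfpt1. The mesenchymal list was past the threshold, with a negative median, without wild-type library 19 (adjusted p = 0.0452 by camera), with the surrogate variable as a covariate (adjusted p = 0.019) and with the macrophage list as a covariate (adjusted p = 5.58e-05). The immediate early list was past it, with a positive median, without wild-type library 20 (adjusted p = 0.0174 by camera) and with library weights (adjusted p = 0.0142). The median and the mean or test differed in sign for the ductal, mesenchymal, glial and neuronal lists and for the genes around P2ry14. The last list includes P2ry14 itself, at −1.97, which lowers its mean. Of the 100 splits of the 20 libraries, the real one included, 37 gave at least as many as 10 lists past the threshold by camera with its preset correlation.

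**Figure D4:**
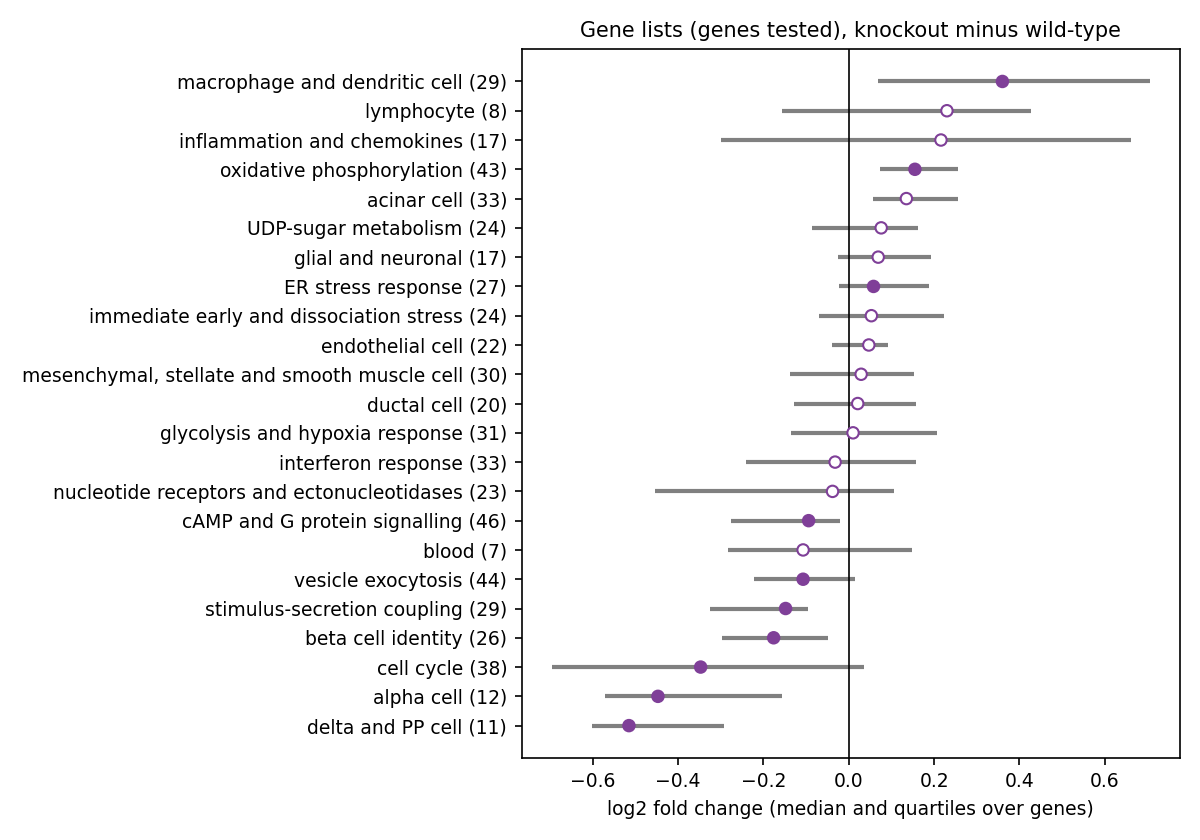
Median log2 fold change, knockout minus wild-type, of each preset gene list, with a bar from the lower to the upper quartile of its genes and the number of genes tested in brackets. Filled points mark the 10 lists past an adjusted p of 0.05 by camera with its preset correlation, of which the delta and PP cell list at −0.52 is the lowest.

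All 20 libraries carried Y-linked transcripts, with Ddx3y between 442 and 1135, and Xist was at most 33.8. Of the 4 sex-linked genes tested, none passed over all genes, and Eif2s3y rose adjusted over the list alone (log2 0.31), beside Uty at 0.16.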

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

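The tests of chromosome 3, of mixed RNA, of acinar RNA and of the ratios of somatostatin and glucagon to insulin were chosen only after the result was seen, as was the fit without chromosomes 3 and 7. A library was singled out where its gap to the next one, relative to the range of its group and taken on log2 of the value plus 1, exceeded Dixon's critical value for 10 samples, and this happened 21 times among 244 groups of values. Chance gives about 1 in 20, or 12.2.

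Knockout replicate 6 stood apart in 5 of these cases. It was the lowest knockout library for Rps13-ps2 (0 reads, ratio 0.803), Myo7a (79.7, ratio 0.704) and Trim12a (0 reads, ratio 0.808), and the highest for Rps13-ps1 (1280, ratio 0.639) and Hist1h2al (195, ratio 0.734). In each case it was nearer the wild-type mean than the mean of the other knockout libraries.

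For this library, RNA of a wild-type library mixed into a knockout library cannot be told apart from other explanations. The share of wild-type RNA needed was taken at 8 genes differing at least 10-fold whose groups, this library aside, did not overlap. It was over 75% at 7 of them and 27.8% at Adgrf4, which alone gave the span of 72.2 percentage points. Variation between libraries of a group was not separated from mixing. A wild-type library labelled knockout stays open and may account for the pattern. At the 74 genes that differed without it, knockout replicate 6 was nearer the wild-type mean in 81.1%. Left out in the same way, the lowest wild-type library was at 65.3%, and the other knockout libraries ran from 3.7% to 39.4%. Knockout replicate 6 lay beyond the wild-type range on the knockout side in 21.6%. There wild-type libraries ran from 0% to 36.7% and the other knockout libraries from 59.1% to 88.9%. Gm4735, at 380 where the highest wild-type library had 20.5, and P2ry14, at 61.7 where the lowest wild-type library had 79.7, lay outside the wild-type range, but neither separates the groups, with knockout replicates 8 and 10 at 11.9 and 3.74 for Gm4735 and knockout replicates 2 and 10 within the wild-type range for P2ry14. At 5 of the 49 genes the groups did not overlap, so this library lay on the knockout side there. It was at 1869 for Enpep, 997 for Edn3, 84.8 for Rpl34 and 79.7 for Myo7a. The nearest wild-type libraries had 2050, 1069, 68.2 and 62.7. Those genes were picked with this library counted as knockout, so its side there was fixed by the choice and decides nothing about its label. A knockout animal carrying other strain segments than the rest of its group stays open as well and was not tested.

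The crowding of differing genes on chromosome 3 could come from chromosome segments that differ between the knockout and wild-type colonies, since the strain is mixed. This was not tested, since the adjusted hypergeometric p of 0.00113 for chromosome 3 measures the crowding itself, and any cause of it would give the same value. Reads moving between near-identical copies cannot be told apart from a difference in the genes themselves. Summed over Rps13 and its 5 named copies, log2 values were higher in knockout by 0.644 (permutation test p = 0.0261), and over Rps15a and its 7 named copies by 0.568 (permutation test p = 0.039), each between the bounds of 0.3 and 1 set for deciding. An effect of the loss of P2Y14 on these genes stays open and is not separated from differing segments by this design, the 10 genes of chromosome 3 lying at places 328 to 753 of its 833 tested genes and P2ry14 at place 174.

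The negative medians of the endocrine lists were weighed against a different makeup of the preparations. More acinar RNA in the knockout preparations was not seen beyond the spread in the acinar list, at 22.6% of reads against 21.5% in wild-type (permutation test p = 0.786). With the acinar score as a covariate the delta and PP cell list kept a median log2 of −0.527. A score so alike in both groups could hardly move that median, so this fit does not decide. Were a smaller share of islet cells of every endocrine type the only cause, the ratio of Sst to Ins2 would not differ. It was lower in knockout (permutation test p = 0.00024). Were a smaller share of delta cells the only cause, the ratio of Gcg to Ins2 would not differ. It was lower as well (permutation test p = 0.00106). The ratios measure transcripts and not cells. Gcg and Sst also belong to the alpha cell and the delta and PP cell lists, so the ratios restate the pattern and do not settle cell shares. Smaller shares of both alpha and delta cells, and an effect of the genotype on transcription in them, may both remain for these 2 lists, and neither was tested.

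Other libraries were singled out as follows. P2ry14 was lowest in knockout replicate 5 (0 reads, ratio 0.721). Trim12a was highest in wild-type library 11 (30.2, ratio 1.0), the other wild-type libraries having 0 reads. Wild-type library 20 was lowest for Rpl34 (14.8, ratio 0.558), Glp1r (4635, ratio 0.467) and Aif1 (0 reads, ratio 0.699). Knockout replicate 2 was lowest for Trpm5 (2540, ratio 0.482), and knockout replicate 10 was lowest for Gfpt1 (4901, ratio 0.489) and Uggt1 (3892, ratio 0.471). Wild-type library 19 was highest for Chac1 (737, ratio 0.482) and lowest for Plk1 (3.73, ratio 0.597), for the score of UDP-sugar metabolism (9.38, ratio 0.481) and for the glial and neuronal score (5.30, ratio 0.617). Wild-type library 14 was highest for the hemoglobin genes Hbb-bs (131400, ratio 0.66) and Hba-a2 (137200, ratio 0.643) and for the blood score (12.17, ratio 0.785), and lowest for the score of cAMP and G protein signalling (10.04, ratio 0.502).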

How the results depend on the processing

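The fits without chromosomes 3 and 7, with deposited size factors in edgeR and with the macrophage score, and the exact rank test, were chosen only after the result was seen. Direction was judged where either fit was past the threshold, for lists by camera, and by this measure no result reversed. The median of the mesenchymal list did turn, from 0.03 to −0.23 without wild-type library 19, −0.19 with the surrogate variable and −0.35 with the macrophage score. No paired analysis was possible because the wild-type columns carry no replicate number of the labels. In place of 49 genes (28 higher, 21 lower), 29 (18 and 11) passed among genes with a mean of at least 100, where fewer genes were tested. Without chromosomes 3 and 7, 24 (14 and 10) passed. Fewer genes were tested there too, but Ptprz1 and Gpr179, on neither chromosome, were tested and lost their calls. Library weights gave 163 (79 and 84), DESeq2 137 (73 and 64), the acinar covariate 82 (45 and 37) and the surrogate variable 82 (46 and 36); the cause was not tested. The rank test with a normal approximation gave 0 (0 and 0), with 1450 genes at an unadjusted p under 0.05, but its smallest p was 0.000132, where the exact rank test reached 1.08e-05 and gave 17 (6 and 11), 13 of them among the 49. With edgeR 43 passed, 12 of them lower and 72.1% higher, and with deposited size factors 42, 11 lower and 73.8% higher, against 57.1% in the limma fit. Of the 49 genes, 49 were shared with library weights, 47 with DESeq2 and 37 with edgeR. P2ry14 passed with DESeq2 (log2 −1.56, adjusted p = 0.0144) and the acinar covariate (−2.10, 0.0339), among adjusted p from 0.0144 to 0.381 over all its fits.

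Leaving out each library gave 27 to 74 genes, 12 to 39 higher and 15 to 35 lower, a log2 fold change of P2ry14 from −2.15 to −1.39 and 8 to 11 lists. P2ry14 passed without knockout replicate 5 (−1.39, 0.0283). Totals were 27, 74, 32 and 32 without knockout replicates 4, 6, 8 and 9 and 31 without wild-type library 19. Higher genes were 12, 16 and 15 without knockout replicates 4, 8 and 9, and 16, 17, 18 and 16 without wild-type libraries 11, 12, 16 and 19. Lower genes were 35 without knockout replicate 6. In knockout replicate 5, 0 reads of P2ry14 allow a normalized read count of up to 4.62. Lower depth does not account for the 0, since knockout replicates 6 and 7 had lower size factors and 24 reads each. At the depth and spread of these libraries together 24% of simulated 1.5-fold changes were recovered, with genes drawn independently, and depth alone was not varied.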

Other observations

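The ratios of hormone transcripts and the splits by estimated correlation below were chosen only after the result was seen. Relative to insulin, glucagon and somatostatin transcripts were lower in knockout islets. The log2 ratio of Gcg to Ins2 was −4.62 ± 0.42 (SD, n = 10) in knockout and −3.90 ± 0.41 (SD, n = 10) in wild-type (permutation test p = 0.00106, adjusted p = 0.00265 over 5 ratios). That of Sst to Ins2 was −8.44 ± 0.26 (SD, n = 10) against −7.75 ± 0.51 (SD, n = 10), with a permutation test p of 0.00024 and an adjusted p of 0.0012. The ratios of Ppy (permutation test p = 0.162), Iapp (0.821) and Ins1 (0.711) to Ins2 did not differ beyond the spread. Ins1 and Ins2 together took 28.1 ± 9.87% of reads (SD, n = 10) in knockout and 28.3 ± 7.61% (SD, n = 10) in wild-type.

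The most abundant transcripts were Ins2, at 26.8% of all reads, and ENSMUSG00000079850, which has no name in the annotation used, at 14.4%. Amy1 followed at 8.22%. The share of the acinar list ran from 6.43% to 33.4% over the 20 libraries.

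The number of genes past the threshold stands apart from chance, as 1 of the 100 splits of the 20 libraries, the real one, gave as many as 49, and the highest other split gave 2. The number of lists does not, as 37 of the 100 splits gave as many as 10 with the preset correlation, and the highest other split gave 17. With an estimated correlation the real split gave 1 list, the delta and PP cell list, and each of the 99 others gave 0.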
